A study of Homo sapiens with 6 samples.

How the data were processed

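Gene expression was measured on Illumina BeadChip arrays, which carry a probe of fixed sequence on many beads and report the mean brightness of those beads. The 6 arrays held RNA of HCT116 cells, an established human colorectal carcinoma line. Of these, 3 came from cells with a control short hairpin RNA (shCtrl) and 3 from cells with a hairpin against TCF7L1 (shTCF7L1), and the series describes the 3 of each condition as biological replicates. Groups and replicate numbers were taken from the sample labels. Per the labels, total RNA was extracted with Trizol, cleaned on RNeasy columns with DNase treatment and turned into biotinylated cRNA.

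The deposited non-normalized table held 47225 probes with 1 intensity and 1 detection p-value per probe and array. The intensity is the average bead signal on a linear scale, per the file headers, and no array-to-array normalization was visible in the values, whose means differed between arrays. The detection p-value, per the file headers, was deposited for each probe and array, and a small value means a signal above the negative control beads. GenomeStudio version 2011.1 made these values, per the submitters' processing notes; other settings are not given in the sources used here. The authors' series matrix held a second set of intensities for 47231 probes, of which 6 were in that table alone and were not used here. On every array the authors' matrix was a straight-line function of the non-normalized signal (r = 1.00 at the printed precision): a background of 27.3 to 28.0 units subtracted, then a factor of 0.978 to 1.08, which gave every array the same mean of 145.7. The authors' array medians lay between 4.70 and 5.37, and 27.8% to 29.7% of the authors' values were at or below 0. The matrix was neither log-transformed nor centred, and it served as an alternative.

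The analysis started from the non-normalized intensities. They were background corrected with normexp, with the negative control mean and spread inferred from the detection p-values, given an offset of 16, quantile normalized and put on the log2 scale with neqc of limma version 3.58.1 in R version 4.3.3. A probe was kept if its detection p lay below 0.01 on at least 3 of the 6 arrays, which left 16835 probes. The platform annotation gave 1 gene symbol for 30110 probes of the table and several for 8 probes, and 17107 probes were not listed there and stay unnamed here. Symbols were brought up to date through Entrez identifiers with the RefSeq gene table of assembly GRCh38.p14. That matched 30074 annotated probes, and 39 that did not match kept the annotation's symbol. Of the kept probes 13665 had a gene. A gene was represented by its kept probe of highest mean over the 6 arrays, giving 10470 genes of the 20046 named on the array. Members of gene lists outside these genes were not analysed here.

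Groups were compared with limma (lmFit and eBayes, 2-sided) on the 6 arrays without a block, and p-values were adjusted with Benjamini-Hochberg over the genes tested. A gene was called changed at an adjusted p below 0.05. Log2 fold changes are shTCF7L1 minus shCtrl. The only TCF7L1 probe did not pass the detection filter, and its values come from the same fit with that probe added. Where no array of a group was above background (detection p below 0.01), the fold is printed as a lower bound. It sets the bright group's mean against the dim group's mean of the higher of the lowest detected signal and the probe's own signal, on normalized log2 values per array. Exact permutation tests of 3 against 3 arrays cannot go below p = 0.1. Gene lists, 31 in number, were fixed before the data were examined, and 28 had at least 5 tested members. These were tested with camera in limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg over the 28 lists. The test was repeated with the correlation estimated from the data and on ranks, and fry was run beside it. With an estimated correlation camera uses only the residual degrees of freedom of the 6 arrays, which makes small p-values harder to reach. Lists share members, so their tests are not independent.

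The genes named in the text follow a rule fixed before the data were examined. It takes TCF7L1 and EPHB3, and the 12 largest positive and 12 largest negative fold changes among changed genes whose groups did not overlap, leaving out provisional symbols. It adds up to 4 changed members of each list with the largest change, or the member of smallest p where none changed. Every changed member of the Wnt target and Eph lists is also named. The rule gave 107 genes. Members named beyond it are said to have been chosen after their values were seen. Of the 107 genes, 27 had other kept probes, and in 25 of these all other probes changed with the same sign.

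The number of arrays limits the precision. Mean bead signal per array was 162 to 177, and 16055 to 17384 probes (34.0% to 36.8%) were detected. On simulated data with the spread of these 10470 genes and 50 changed genes per size, the shTCF7L1 against shCtrl fit recovered 2% of genes changed by 0.5 on the log2 scale, 46% at 1, 86% at 1.5 and 88% at 2, and 1.77% of its calls were false. Only 200 genes changed in the simulation, against 1566 called in the data. The Benjamini-Hochberg cut-off is stricter when fewer genes change, so these shares do not give the power of the real comparison. In the simulated lists the shifted list was called and, of 30 unshifted lists, 0 were called by camera. The simulated genes were drawn independently, so false calls from correlation among members were not covered. Alternatives covered background correction and offset, median scaling, the authors' values (values below 0 set to 0, then log2 after adding 16), the detection filter, the probe rule, the variance model, array weights, a replicate block, thresholds, a test against a 1.2-fold minimum, and leaving out each array in turn. Figures were drawn with matplotlib version 3.10.9.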

Results

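Transcript levels were measured in 6 RNA samples of HCT116 cells, an established human colorectal carcinoma line, on Illumina expression arrays. The control group (shCtrl) and the knockdown group (shTCF7L1) had 3 arrays each. TCF7L1 is a member of the TCF/LEF family of DNA-binding proteins that act in Wnt signalling. The series asks which transcripts differ between control and TCF7L1 knockdown cells. Between 34.0% and 36.8% of probes were detected per array. Across the 10470 tested genes the arrays correlated at 0.971 to 0.975 within a group and at 0.942 to 0.948 between groups. The first principal component, 51.4% of the variance, separated the groups. The second, 13.6% of the variance, set shTCF7L1 replicate 3 (24.9) apart from shTCF7L1 replicates 1 and 2 (-13.9 and -12.5). All arrays lay on 1 chip with each group on its own run of neighbouring positions, so position on the chip and group cannot be told apart.

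The TCF7L1 probe (ILMN_1733841) was dim in all arrays and lower in the knockdown. Its bead signal was 45.1, 35.8 and 40.6 in the shCtrl arrays and 29.3, 32.4 and 25.4 in the shTCF7L1 arrays. It was above background on 2 of the 3 control arrays and on 0 of the 3 knockdown arrays. The normalized log2 level was 4.87 ± 0.19 in shCtrl and 4.34 ± 0.10 in shTCF7L1 (SD, n = 3 each), a log2 difference of -0.53 (SE 0.20). Control signal was at least 1.02-fold higher, counted against the detection limit. The difference did not pass the threshold in limma (adjusted p = 0.0800), and the exact 2-sided permutation p was 0.1, the smallest that 3 against 3 arrays allow. The log2 difference was -0.69 with the authors' processed values, where it passed (adjusted p = 0.0321), and -0.22 with a background offset of 50 (adjusted p = 0.271), the lowest and highest p of the alternatives.

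EPHB3, an Eph receptor gene studied in relation to TCF7L1 in colorectal cancer cells, was also close to background (probe ILMN_1741346). Its log2 level was 4.78 ± 0.12 in shCtrl and 4.87 ± 0.45 in shTCF7L1 (SD, n = 3 each). The log2 difference of 0.09 (SE 0.23, 95% interval -0.40 to 0.57) was smaller than the spread between arrays (limma adjusted p = 0.842). That interval spans 0.757-fold to 1.49-fold. The probe was above background on 1 of 3 control arrays and 2 of 3 knockdown arrays, and without shTCF7L1 replicate 2 the difference was -0.09. The Eph receptor and ephrin list held 10 tested members, of which EPHA4 rose (log2 0.93, SE 0.21, adjusted p = 0.00725) and 9 did not pass. Adjusted over the list alone, 2 members passed, 1 in each direction. The list did not pass (camera adjusted p = 0.902), and without shCtrl replicate 3, 2 members passed.

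**Figure D1:**
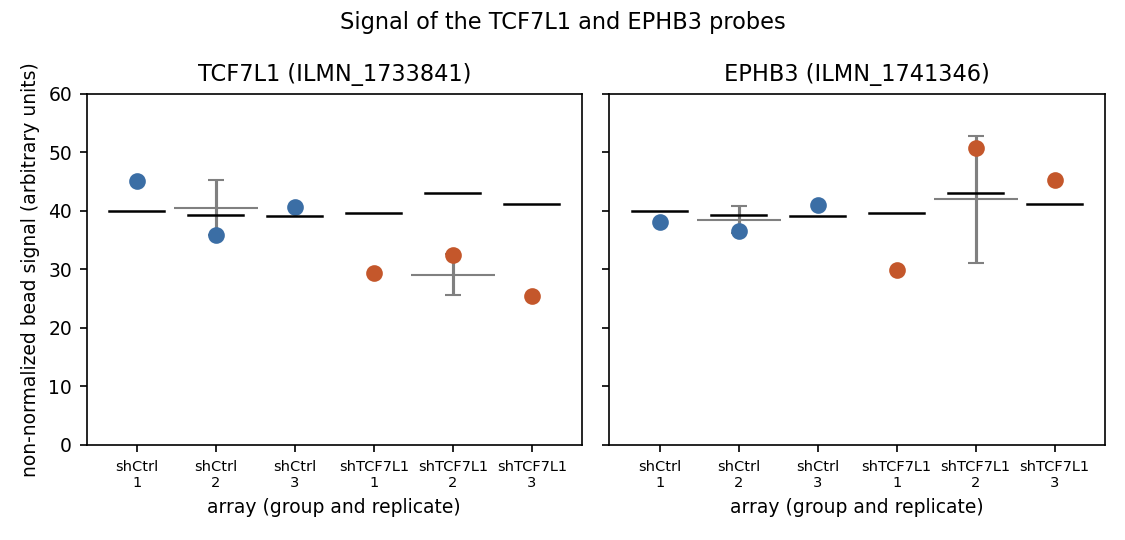
Non-normalized bead signal (arbitrary units) of the TCF7L1 and EPHB3 probes on each array; points are arrays (blue shCtrl, orange shTCF7L1), grey lines are group means with SD (n = 3), and short black lines mark the lowest signal detected on that array. The TCF7L1 points lie between 25.4 and 32.4 in shTCF7L1 and between 35.8 and 45.1 in shCtrl, and the EPHB3 groups overlap.

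The largest increase in shTCF7L1 cells was that of CPA4, a secreted carboxypeptidase, at 13.8-fold (log2 3.79, SE 0.26, adjusted p = 4.85e-07). Next came MAMDC2 (5.23-fold, SE 0.20 on the log2 scale), the matrix proteoglycan versican VCAN (5.14-fold, SE 0.24) and PGM2L1 (4.65-fold, SE 0.22). The Wnt antagonist DKK4 rose 4.27-fold (SE 0.23) and the AP-1 subunit JUN 4.18-fold (SE 0.21). STK40, SNAR-A1, ZBTB20, ITPRIPL2 and the zinc finger factor KLF6 rose between 3.67-fold and 4.02-fold. NRP1, a co-receptor for semaphorins and VEGF, was not above background in any control array and rose at least 2.89-fold (adjusted p = 1.47e-05). In each of these genes all 3 knockdown values lay above all 3 control values. Fold sizes depend on the background setting: with an offset of 50 the log2 value of CPA4 was 3.01.

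The largest decrease was that of BNIP3, a mitochondrial protein induced in hypoxia, which fell by 3.22 on the log2 scale (9.31-fold, SE 0.20, adjusted p = 2.07e-07). ANKRD37, another hypoxia-induced gene, fell 8.16-fold (SE 0.24). RRM2, the small subunit of ribonucleotide reductase, fell 6.0-fold (SE 0.21), and the spindle genes HMMR and MAD2L1 fell 5.34-fold (SE 0.22) and 4.37-fold (SE 0.19; another MAD2L1 probe gave -1.36 on the log2 scale). PHGDH, which starts serine synthesis from a glycolytic intermediate, fell 4.56-fold (SE 0.21). TMEM14A, CAPZA2, APIP and RCN1 fell between 3.99-fold and 5.35-fold. The BRWD1 probe fell 6.21-fold, while 2 other kept probes of that gene fell by 0.50 on the log2 scale. The ANXA2 probe fell 4.50-fold and its 2 other kept probes gave -1.75 and -3.19 on the log2 scale. Probes of its near-identical copies ANXA2P1 (-1.90) and ANXA2P3 (-1.78) were lower too, and that of ANXA2P2 changed by -0.14 (adjusted p = 0.673), so which transcript each probe reads is uncertain. These copies were chosen after their values were seen. With a background offset of 50, ANKRD37 gave -2.34 and RRM2 -1.92 on the log2 scale, and with the mean of its probes BRWD1 gave -1.21.

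Over all genes, 1566 of 10470 changed (15%), 822 higher and 744 lower in shTCF7L1, and 3125 had an unadjusted p below 0.05. With the authors' processed values the split was 1152 higher and 558 lower, so 67.4% of calls were increases against 52.5% here. At least 2-fold changes numbered 222 upward and 223 downward. In 1550 of the changed genes the groups did not overlap; over all genes this held for 33.9%, where chance gives 10%. For 69 changed genes 1 group was not above background, so their fitted fold changes are no bound. The count was 1010, 987 and 1002 without shCtrl replicates 1, 2 and 3, and 1040 and 1034 without shTCF7L1 replicates 1 and 2.

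**Figure D2:**
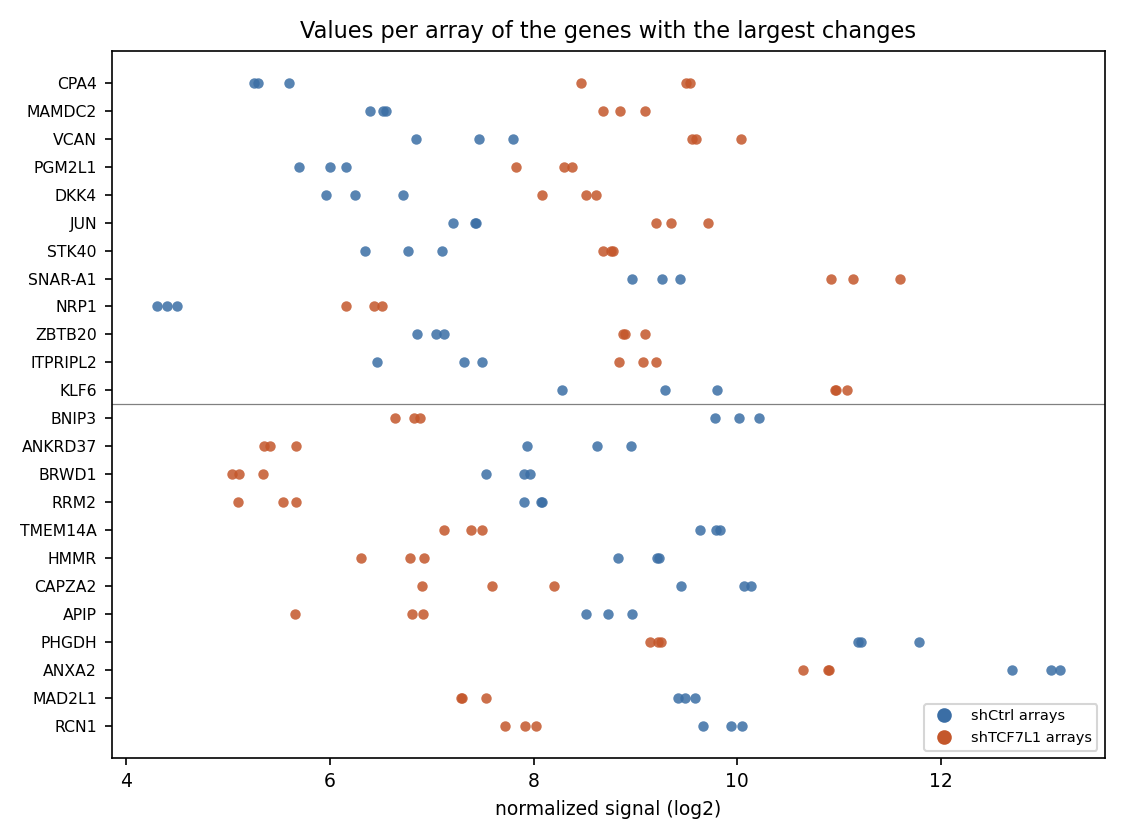
Normalized log2 signal (horizontal axis) of the 12 genes with the largest increase (upper block) and the 12 with the largest decrease (lower block); each point is 1 array, blue shCtrl and orange shTCF7L1. Within every gene the 3 values of one group lie apart from the 3 of the other, and levels of different genes are not comparable.

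Genes of mitosis fell together in shTCF7L1 cells. Of 46 tested members 30 fell and 16 did not pass, and 38 fell when adjusted over the list alone. The list's median log2 fold change was -0.85, and 45 of 46 members had a negative value. HMMR and MAD2L1 are given above; the phosphatase CDC25C, which activates CDK1, fell 3.88-fold (SE 0.19) and topoisomerase TOP2A 3.48-fold (SE 0.20). Of CDC25C, 2 other probes gave -0.80 and -1.81 on the log2 scale, and with a background offset of 50 its value was -1.36. Camera gave an adjusted p of 4.97e-23 with the preset correlation and an adjusted p = 0.00699 with an estimated correlation, the one list of 28 that passed both. Between 25 and 29 members fell when any single array was left out.

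DNA replication and G1/S genes moved less as a group. Of 40 tested members 8 fell, 1 rose and 31 did not pass, with a median of -0.13 (-0.24 to -0.075 over the alternatives). Besides RRM2, the polymerase genes POLA1 (-1.02, SE 0.23) and POLE2 (-0.93, SE 0.24) fell, and the licensing factor CDT1 rose (0.98, SE 0.22). When adjusted over the list alone, 11 fell and 2 rose. The list did not pass (camera adjusted p = 0.0724, 0.0406 to 0.456 over the alternatives), except with median scaling, the authors' values or the mean of probes, or without shTCF7L1 replicate 1 (0.0479). Without any one of the 3 control arrays, or without shTCF7L1 replicate 3, 4 members passed in place of 9, and POLE2 did not pass without shCtrl replicates 2 or 3 or shTCF7L1 replicate 3. Without a detection filter neither POLA1 (0.0536) nor POLE2 (0.0907) passed.

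Hypoxia and glycolysis genes shifted downward. Of 35 members 13 fell and 22 did not pass, and 14 fell when adjusted over the list alone. The list's median was -0.24, and -0.37 to -0.13 over the alternatives. With BNIP3 and ANKRD37 fell the hypoxia-induced repressor BHLHE40 (3.94-fold, SE 0.22), the aldolase gene ALDOC (2.61-fold, SE 0.19) and PGK1, an enzyme of glycolysis (1.83-fold, SE 0.21). Of the 22 other members 13 had values above 0. Camera gave an adjusted p of 0.00129, and an adjusted p = 0.0937 with an estimated correlation. PGK1 did not pass without shCtrl replicate 2 or shTCF7L1 replicate 2 (adjusted p up to 0.0636).

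Cholesterol synthesis genes shifted downward as well, with 6 of 24 members lower, 18 not past the threshold and a median of -0.36. EBP fell by 1.07 on the log2 scale (SE 0.21), SQLE, which encodes squalene epoxidase, by 0.85 (SE 0.20) and INSIG1 by 0.84 (SE 0.20). MSMO1 fell by 0.81 (SE 0.21), while its other probes gave values between -0.55 and 0.12. Adjusted over the list alone, 6 fell as well. The camera test gave an adjusted p of 0.00255, and an adjusted p = 0.0937 with an estimated correlation. Without shCtrl replicate 3 or shTCF7L1 replicate 3, 3 members fell, and MSMO1 did not pass without either of these or shCtrl replicate 1, nor with the mean of its probes (adjusted p up to 0.138).

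In the list of ER stress and amino acid response genes 6 of 29 members fell, 1 rose and 22 did not pass, with a median of -0.27 and the same counts adjusted over the list alone. Among those that fell were PHGDH, the folate enzyme MTHFD2 (-1.05, SE 0.24), the amino acid transporter SLC7A5 (-0.82, SE 0.22) and the pseudokinase TRIB3 (-1.23, SE 0.20). The member that rose was the stress factor ATF3 (0.74, SE 0.20), chosen after its value was seen. Camera gave an adjusted p of 0.00264, and an adjusted p = 0.0937 with an estimated correlation. Without shCtrl replicate 1, 3 members passed, and without shCtrl replicate 3 or shTCF7L1 replicates 1 or 2, 4 passed. In these 4 fits 0 members rose, and SLC7A5 did not pass without shCtrl replicates 1 or 2 or shTCF7L1 replicate 2 (adjusted p up to 0.10). Without a detection filter neither SLC7A5 nor MTHFD2 passed.

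Oxidative phosphorylation genes had a median of -0.21, with 3 of 35 members lower, 1 higher and 31 not past the threshold. NDUFB5 (-0.93, SE 0.22), NDUFB3 (-0.72, SE 0.23) and COX5B (-0.87, SE 0.28), subunits of respiratory chain complexes, and ATP5F1D of the ATP synthase (0.71, SE 0.22) passed. The other probe of NDUFB3 gave -0.25 and that of ATP5F1D -0.16, and neither gene passed with the mean of its probes. Adjusted over the list alone, 1 member passed. For the list, camera gave an adjusted p of 0.0468, and an adjusted p = 0.261 with an estimated correlation. The list did not pass with detection required on all arrays (0.0537), or without shCtrl replicate 2 (0.121), shCtrl replicate 3 (0.0627) or shTCF7L1 replicate 1 (0.0808), and 1 or 2 members passed when any single array was left out. NDUFB5 did not pass without shTCF7L1 replicate 1 (0.0559), COX5B without any one array except shTCF7L1 replicate 2 (up to 0.199), and NDUFB3 and ATP5F1D without any one array except shTCF7L1 replicate 1 (NDUFB3 up to 0.726). None of these 4 genes passed without a detection filter, COX5B did not pass with a background offset of 50, array weights or the mean of probes, and ATP5F1D not with median scaling.

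Genes listed as p53 targets shifted upward, with 7 of 29 members higher, 1 lower and 21 not past the threshold. The list's median was 0.49, and 0.32 to 0.59 over the alternatives. The cell cycle inhibitor CDKN2B rose by 1.00 on the log2 scale (SE 0.20), PHLDA3 by 0.95 (SE 0.22), the secreted stress factor GDF15 by 0.90 (SE 0.22) and the nuclease AEN by 0.77 (SE 0.23; its other probe gave 0.28). With p adjusted over the list alone, 14 rose and 2 fell. GADD45B passed (-0.58, SE 0.19) but with any single array left out 0 members fell, and CDKN1A, a well-known p53 target, gave -0.09 (SE 0.29, adjusted p = 0.871), both genes chosen after their values were seen. Camera gave an adjusted p of 0.00264, and an adjusted p = 0.0937 with an estimated correlation. The count past the threshold, 8, was 4 without shCtrl replicate 1, shCtrl replicate 3 or shTCF7L1 replicate 2, 3 without shCtrl replicate 2 and 5 without shTCF7L1 replicate 1. AEN did not pass without shCtrl replicates 1 or 2 or shTCF7L1 replicates 1 or 2 (adjusted p up to 0.149), with the mean of its probes or without a detection filter, and GDF15 not without shCtrl replicates 2 or 3 (up to 0.0630) or a detection filter.

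In the list of Hippo/YAP target genes 6 of 20 members rose, 2 fell and 12 did not pass, with a median of 0.32. The ecto-nucleotidase NT5E rose 3.55-fold (SE 0.20), the phosphatase PTPN14 2.70-fold (SE 0.22) and the matrix protein CCN1 2.42-fold (SE 0.22). YAP1, counted in the list though it is the coactivator of the pathway and not a target, fell 3.16-fold (SE 0.22). The receptor kinase AXL fell 1.84-fold (SE 0.20), and its other probe gave -0.56 on the log2 scale. The counts adjusted over the list alone were 7 higher and 2 lower. Camera gave an adjusted p of 0.0468, and an adjusted p = 0.435 with an estimated correlation. The list did not pass in 9 of 19 alternatives: that one, camera on ranks (0.0790), no background correction (0.0538), a background offset of 50 (0.0671, median 0.15), detection on all arrays (0.0537), a looser detection filter (0.0622), and without shCtrl replicate 3 (0.132), shTCF7L1 replicate 1 (0.0711) or shTCF7L1 replicate 3 (0.132).

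**Figure D3:**
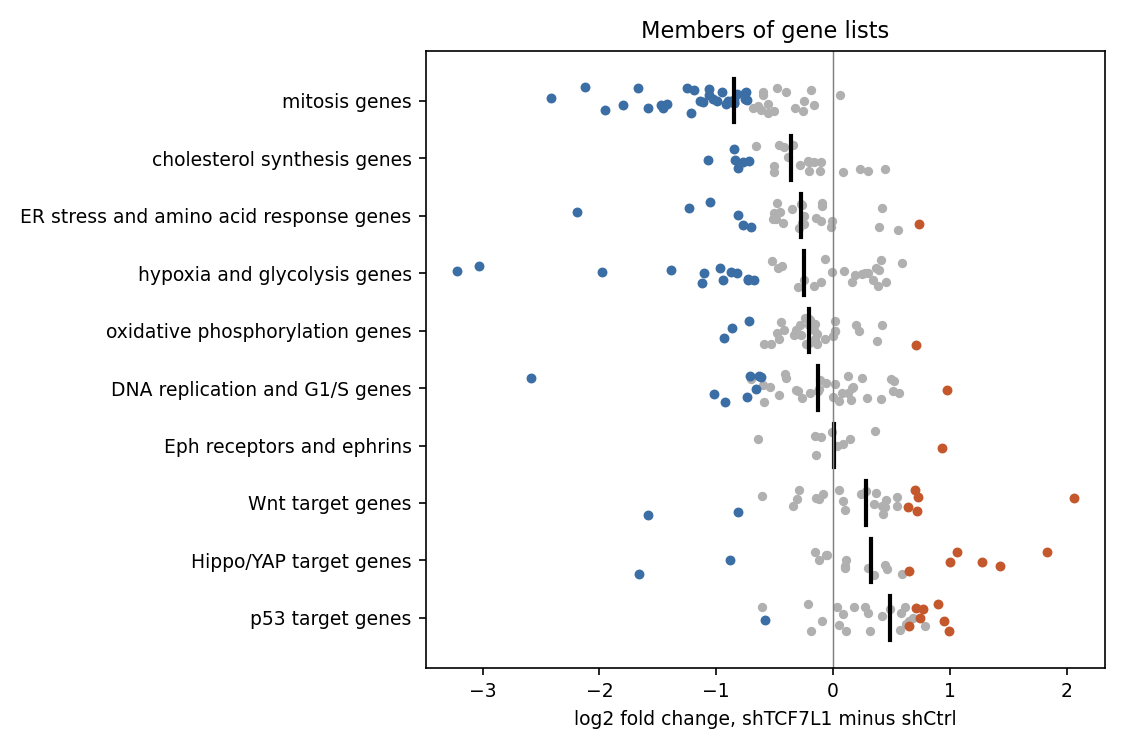
Log2 fold change (shTCF7L1 minus shCtrl) of the tested members of the 7 lists that passed camera and of 3 further lists; each point is a gene, blue lower and orange higher at an adjusted p below 0.05, grey not past it, and black bars are list medians. The mitosis median lies at -0.85, the Wnt target median at 0.28 and the Eph median at 0.01.

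Wnt target genes moved in both directions. Of 27 tested members 5 rose, 2 fell and 20 did not pass, with a median of 0.28. JUN rose 4.18-fold, TSPAN5 1.65-fold (SE 0.20) and MYC 1.64-fold (SE 0.20; log2 0.72, and 0.29 for its other probe). The cyclin CCND1 (1.63-fold, SE 0.23) and CCDC88C (1.56-fold, SE 0.21) also passed. CCND1 did not pass without any one of the 3 control arrays or shTCF7L1 replicates 1 or 3 (adjusted p up to 0.177), with median scaling, the authors' values or array weights, or without a detection filter. CCDC88C did not pass without shCtrl replicates 2 or 3 or any one shTCF7L1 array (adjusted p up to 0.180), with array weights, a trended robust variance or a background offset of 50, or without background correction or a detection filter. BIRC5, which encodes survivin and is also on the mitosis list, fell 2.99-fold (SE 0.19; log2 -1.58, and -0.52 for its other probe), and SLC7A5 fell 1.76-fold (SE 0.22). The counts adjusted over the list alone were 6 higher and 2 lower. As a whole the list did not pass (camera adjusted p = 0.218, 0.0885 to 0.456 over the alternatives). The count past the threshold, 7, was 3 without shCtrl replicate 2 or shTCF7L1 replicate 1 and 4 without shCtrl replicate 3 or shTCF7L1 replicate 3. Calls ended for TSPAN5 without shCtrl replicate 2 or shTCF7L1 replicates 1 or 3, for MYC without shCtrl replicates 1 or 3 or shTCF7L1 replicate 1 and with the mean of its probes, and for SLC7A5 without shCtrl replicates 1 or 2 or shTCF7L1 replicate 2 (adjusted p up to 0.0868, 0.0892 and 0.10). SLC7A5 also did not pass without a detection filter.

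Of 29 Wnt pathway components 3 rose, 1 fell and 25 did not pass, with the same counts adjusted over the list alone and a median of 0.28. TCF7L2, a relative of TCF7L1, rose 3.01-fold (log2 1.59, SE 0.21, adjusted p = 0.000214). WLS, which carries Wnt proteins to the cell surface, rose 2.33-fold (SE 0.19; log2 1.22, and 0.58 to 1.22 for 4 other probes), and CTNNBIP1, an inhibitor of beta-catenin, rose 1.70-fold (SE 0.20). The kinase gene GSK3B fell 1.57-fold (SE 0.20). The list's camera adjusted p was 0.0862. GSK3B did not pass when any single array was left out (adjusted p up to 0.159), with median scaling, with the authors' values or without a detection filter. CTNNBIP1 did not pass without shCtrl replicates 2 or 3 or shTCF7L1 replicates 1 or 2 (adjusted p up to 0.0687), where 2 members passed.

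Immediate early and MAPK feedback genes split, with 10 of 33 higher, 3 lower and 20 not past the threshold, the same counts adjusted over the list alone and a median of 0.25. JUN and the MAPK phosphatases DUSP5 (2.21-fold, SE 0.21) and DUSP4 (2.20-fold, SE 0.22) rose. EGR1 fell 2.44-fold (SE 0.22), as did FOS (-0.95, SE 0.19) and IER2 (-0.98, SE 0.23), the last pair chosen after their values were seen. Camera did not set the list apart from other genes (adjusted p = 0.226), while by fry it passed upward (adjusted p = 0.00483). Without shTCF7L1 replicate 1, 8 members passed (5 higher, 3 lower). It was 6 higher and 3 lower without shCtrl replicate 1, and 6 higher and 4 lower without shCtrl replicate 3.

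Apoptosis regulators had 5 of 17 members higher and 1 lower (7 past the threshold adjusted over the list alone; camera adjusted p = 0.387). The survival gene BCL2L1 (0.92, SE 0.22), the BH3 gene BIK (0.89, SE 0.23) and the caspase-8 inhibitor gene CFLAR (0.79, SE 0.21) rose, and CASP9 fell (-0.84, SE 0.21). The count past the threshold, 6, was 3 without shCtrl replicate 1, 1 without shCtrl replicate 2 and 2 without shTCF7L1 replicate 2. BCL2L1 did not pass without shCtrl replicate 3, BIK without shCtrl replicates 1 or 2 or shTCF7L1 replicate 1, and CFLAR and CASP9 without shCtrl replicate 2 or shTCF7L1 replicate 2 (adjusted p up to 0.0792). BCL2L1 and BIK also did not pass without a detection filter, nor CFLAR with a background offset of 50. In the TGF-beta and BMP list 4 of 23 rose and 1 fell (6 passed adjusted over the list alone; adjusted p = 0.426). The decoy receptor gene BAMBI (1.2, SE 0.30), TGIF2 (1.00, SE 0.28) and the receptor gene ACVR2A (0.94, SE 0.22) rose, and ID2 fell (-0.86, SE 0.22). The count past the threshold, 5, was 3 without any one control array, 1 without shTCF7L1 replicate 1 and 2 without shTCF7L1 replicate 2. Without shCtrl replicate 1, 1 member rose and 2 fell, and BAMBI, TGIF2 and ACVR2A did not pass. BAMBI also did not pass without shTCF7L1 replicates 1 or 2, TGIF2 without shTCF7L1 replicates 1 or 3, and ID2 without shCtrl replicates 2 or 3 or shTCF7L1 replicates 1 or 2, and none of these 3 passed without a detection filter (adjusted p up to 0.158).

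Epithelial genes had 4 of 23 members lower and 1 higher, also adjusted over the list alone (5 past the threshold; camera adjusted p = 0.426). Their median was -0.03, and -0.22 to 0.05 over the alternatives. The epithelial factors ELF3 (-0.99, SE 0.20) and ESRP1 (-0.95, SE 0.22), the tight junction gene CLDN7 (-0.88, SE 0.25) and keratin KRT8 (-0.82, SE 0.24) fell. JUP rose (0.70, SE 0.19), chosen after its value was seen. Any one control array left out gave 3 members, and shTCF7L1 replicate 1 left out gave 2. CLDN7 did not pass without shCtrl replicates 1 or 3 or shTCF7L1 replicates 1 or 3, nor without a detection filter (adjusted p up to 0.131), KRT8 without shCtrl replicates 2 or 3, shTCF7L1 replicates 1 or 2 or a detection filter (up to 0.137), and 0 members rose without shCtrl replicates 1 or 2 or shTCF7L1 replicate 1. Of 16 mesenchymal genes 2 rose and 2 fell (the same adjusted over the list alone; adjusted p = 0.645). TGFBI, an extracellular matrix protein, was not above background in control cells and rose at least 2.20-fold. CCN1 also rose, while AXL and SERPINE2 (-0.78, SE 0.19) fell. Without shTCF7L1 replicate 2, 1 rose and 1 fell, since SERPINE2 did not pass (adjusted p = 0.0525) and TGFBI was not tested. Cell migration and adhesion genes had 6 of 32 higher and 3 lower, the same adjusted over the list alone (adjusted p = 0.284). The GTPase RHOB (1.13, SE 0.21), ANXA1 (0.97, SE 0.22) and laminin LAMC1 (0.92, SE 0.23) rose, and ANXA2 fell. The count past the threshold, 9, was 5 without shCtrl replicate 1 or shTCF7L1 replicate 1 and 4 without shCtrl replicate 2, and LAMC1 did not pass without shCtrl replicate 1 or shTCF7L1 replicate 2, nor without a detection filter (adjusted p up to 0.0752).

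Of 31 interferon response genes 3 fell, also when adjusted over the list alone, and 28 did not pass: IRF7 fell 3.15-fold (SE 0.22), PSMB9 1.97-fold (SE 0.20) and IFI6 1.76-fold (SE 0.20). It did not pass as a list (camera adjusted p = 0.0724), except without shCtrl replicate 1 (0.0496), and IFI6 did not pass without shCtrl replicate 2 (0.0566). In the NF-kB and cytokine list (13 members) and the Notch list (21 members) the smallest p belonged to NFKB2 (0.62, SE 0.21, adjusted p = 0.0593) and HES4 (-0.85, SE 0.29, adjusted p = 0.0598). Neither list passed (camera adjusted p = 0.898 and 0.915), and 0 members of either passed adjusted over the list alone. NFKB2 passed without shCtrl replicate 1 and with median scaling, the authors' values or the mean of its probes, and HES4 without shTCF7L1 replicate 1 and with median scaling. In the NF-kB list 1 member passed without shCtrl replicate 1 or shTCF7L1 replicate 2, and in the Notch list 1 without shTCF7L1 replicate 1.

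Among 13 intestinal stem cell genes BMI1 fell (-0.69, SE 0.22; list adjusted p = 0.536). Among 10 enterocyte genes KRT8 and the carbonic anhydrase CA2 (-0.72, SE 0.20) fell and CEACAM1 rose (0.77, SE 0.20; list adjusted p = 0.800). Among 10 pluripotency genes FOXA2 rose (1.41, SE 0.23, and 0.82 with a background offset of 50; list adjusted p = 0.676), and among 17 heat shock genes HSPH1 passed (0.59, SE 0.19; list adjusted p = 0.915). Adjusted over the list alone, the counts past the threshold were 0 for the stem cell and heat shock lists, 5 for the enterocyte list and 1 for the pluripotency list. HSPH1 did not pass when any single array was left out (adjusted p up to 0.120), with median scaling or with the authors' values. BMI1 did not pass without shCtrl replicates 1 or 2 or shTCF7L1 replicates 1 or 3 (adjusted p up to 0.157), with median scaling, with the authors' values or without a detection filter. The 3 enterocyte calls became 1 without shCtrl replicates 2 or 3 or shTCF7L1 replicate 2: KRT8 did not pass without any of these, shTCF7L1 replicate 1 or a detection filter, CA2 without shCtrl replicates 1 or 2 or shTCF7L1 replicates 2 or 3, and CEACAM1 without shCtrl replicate 3 or with a background offset of 50. In the stem cell list 2 members passed without shTCF7L1 replicate 2, and in the pluripotency list 2 without shTCF7L1 replicates 1 or 3.

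Ribosome biogenesis genes had 2 of 30 members higher, SRM (0.84, SE 0.23) and POLR1B (0.84, SE 0.22; 0.50 for its other probe), also adjusted over the list alone (camera adjusted p = 0.426). These 2 became 0 without shCtrl replicate 2 or shTCF7L1 replicate 3, 1 without shCtrl replicate 1 or shTCF7L1 replicate 1, and there were 3 without shCtrl replicate 3. Neither SRM nor POLR1B passed without a detection filter. Of 42 ribosomal protein genes RPL37 (1.09, SE 0.25; 0.51 for its other probe) and RPS23 (0.77, SE 0.24) rose and RPL4 (-1.0, SE 0.28) fell, and 1 passed adjusted over the list alone. That list did not pass here (adjusted p = 0.591) and passed with median scaling and with the authors' values (lowest adjusted p 0.0465). RPS23 and RPL4 did not pass without shCtrl replicates 2 or 3 or shTCF7L1 replicates 1 or 3, where 1 member passed, and none of the 3 genes passed without a detection filter. Of 16 housekeeping genes GUSB rose (0.89, SE 0.22) and PGK1 and PPIA (-0.72, SE 0.21) fell, the same adjusted over the list alone (list adjusted p = 0.733). Without shCtrl replicates 2 or 3 or shTCF7L1 replicate 2, 1 of these 3 passed. PGK1 did not pass without shCtrl replicate 2 or shTCF7L1 replicate 2, GUSB without shCtrl replicate 3, and PPIA without any of these arrays, shTCF7L1 replicate 1 or with the authors' values, and neither GUSB nor PPIA passed without a detection filter. Of markers of other cell types, the fibroblast list had 2 tested members, the collagens COL1A1 (1.14, SE 0.28) and COL6A1 (1.00, SE 0.20), and both rose. COL1A1 did not pass without shCtrl replicate 1 or shTCF7L1 replicate 1, which left 1, nor without a detection filter (adjusted p up to 0.111). The endothelial and neural list had 3, of which SNAP25 rose (1.42, SE 0.24, and 0.79 with a background offset of 50) and TUBB3 fell (-1.21, SE 0.22). Of 5 leukocyte markers the smallest p belonged to CORO1A (-0.32, SE 0.19, adjusted p = 0.274). The leukocyte list's median was 0.06 and fry gave an upward direction, while camera gave a downward one (adjusted p = 0.959). The goblet and enteroendocrine list had 2 tested members, with FCGBP at 0.19 (SE 0.21, adjusted p = 0.597). By fry, which tests whether a list's members move one way on balance and does not compare them with other genes, 12 of the 28 lists passed, the 7 that passed camera and those of Wnt pathway components, DNA replication and G1/S, interferon response, immediate early and MAPK feedback, and cell migration and adhesion genes, and 26 passed its mixed test of change in either direction.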

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

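Of the 3170 kept probes for which the annotation used here lists no gene, 154 were higher in the shTCF7L1 arrays than in the control arrays, a signal outside the gene comparison. Another 177 of these probes were lower, so 10.4% of them changed, against 13.6% of the kept probes with a gene. The test was limma over all kept probes. No explanation was tested for this group.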

How the results depend on the processing

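The counts of members per list with an array left out were chosen after seeing the data. The other alternatives were chosen before. Across settings of background, scaling, filter, probe rule, variance model, weights and block, the number of changed genes stayed within 1.5 times of 1566, and 979 to 1563 of the 1566 were shared. The lowest number shared was without a detection filter (1115 genes called of 20043 tested). A stricter adjusted p of 0.01 left 626 genes (312 higher, 314 lower), and a test against a 1.2-fold minimum left 489 (244 higher, 245 lower), by construction. Leaving out 1 array gave 987 to 1138 changed genes (498 to 572 higher, 463 to 566 lower), with fewer arrays in the fit. With the authors' values the median log2 fold change of all genes was 0.10, against 0.02. TCF7L1 was -0.69 (adjusted p = 0.0321) with the authors' values and -0.22 (adjusted p = 0.271) with a background offset of 50, and the cause was not tested. With an array left out it ranged from -0.64 to -0.44, and EPHB3 from -0.090 to 0.34. The number of lists shifted fell from 7 to 1 with the estimated correlation, and was 5 to 8 with an array left out. Estimated correlations were -0.0097 for hypoxia, -0.015 for cholesterol, -0.0050 for ER stress and -0.0095 for p53 genes. These lie below the preset 0.01, so correlation among members does not account for the loss of these lists. For oxidative phosphorylation (0.015) and Hippo/YAP genes (0.091) the estimate was higher. With the background offset of 50, fold changes were smaller by over 1.5 times for CPA4, NRP1, ANKRD37, BRWD1, RRM2, CDC25C, TGFBI, FOXA2 and SNAP25. Log2 medians of several lists shrank too. They were -0.15 against -0.24 for hypoxia, 0.18 against 0.28 for Wnt pathway and 0.15 against 0.32 for Hippo/YAP genes. Over all alternatives medians ranged from 0.10 to 0.39 for Wnt pathway and from 0.074 to 0.36 for Wnt target genes. No named gene besides EPHB3 turned direction in any setting where it was tested. Of 105 named genes, 30 lost their call without a detection filter. With an array left out 18 to 27 lost it, of 105 tested without a control array and 103 without a knockdown array.

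Same-numbered arrays did not deviate together (r = -0.011, -0.007 and -0.006), so no pairing by number shows in the values. The labels do not say whether a number marks a shared batch. The fit with the replicate number as a block called 1451 genes (765 higher, 686 lower). TCF7L1 was then -0.53 and EPHB3 0.09, 7 lists passed, and 5 named genes (CCND1, CCDC88C, GSK3B, HSPH1 and NDUFB3) lost and 1 (HES4) gained a call.

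Lists whose camera direction turned had not passed to begin with, and the cause was not tested. Their medians were -0.0021 for enterocyte genes without a detection filter and 0.085 when detected on all arrays, and -0.15 for NF-kB genes when detected on all arrays. Heat shock genes gave -0.042 with median scaling and 0.0037 with the authors' values, and Notch genes 0.0031 without a detection filter. Leukocyte markers gave 0.12 with the authors' values, 0.056 with the looser filter and 0.10 with the mean of probes. With an array left out the ranges were -0.13 to 0.16 for Eph genes, -0.0013 to 0.19 for mesenchymal, -0.10 to 0.15 for NF-kB, -0.019 to 0.12 for heat shock and 0.020 to 0.12 for Notch genes. The leukocyte list had too few members for a test in some alternatives, among them detection on all arrays, and has no value there. Signal close to background limits TCF7L1 and EPHB3.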

Other observations

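The tests of a second probe, of matched lists and of mitosis against G1/S genes were chosen after the results were seen, and the families were formed from gene symbols after the data were examined. Family members named below beyond the rule were also chosen after their values were seen.

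Collagen genes were higher in shTCF7L1 cells. Of 11 tested genes with COL symbols 5 rose and 6 did not pass, with a median log2 fold change of 0.73. COL4A5, a basement membrane collagen, rose 3.00-fold (log2 1.59, SE 0.21), COL12A1 2.25-fold (SE 0.20) and COL6A1 2.00-fold (SE 0.20). Intraflagellar transport genes, which serve cilia, were lower: 5 of 15 IFT genes fell, with a median of -0.49, among them IFT46 (-1.02, SE 0.20), IFT52 (-0.89, SE 0.21) and IFT56 (-0.89, SE 0.20). The hypothesis was that genes of one family move together, and of 123 families with 10 or more tested genes 2 passed camera, COL (adjusted p = 0.00514) and IFT (adjusted p = 0.00910). Neither passed with an estimated correlation (adjusted p = 0.632 for both). That test uses only the residual degrees of freedom of 6 arrays, and its power over 123 families was not measured. The mitosis list passed it (camera adjusted p = 0.00699 over 28 lists), so a strong shift can pass. Each family passed 1 form of the test and not the other, so the hypothesis stays open for both families. Both kept their direction and passed with median scaling, with the authors' values, without background correction and with a background offset of 50, with medians of 0.46 to 0.88 for COL and -0.44 to -0.38 for IFT.

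SNAR-A1, a short noncoding RNA, was among the largest increases, and a further hypothesis was that short RNAs were more abundant in the knockdown RNA. The 107 tested genes of small nucleolar and Cajal body RNAs had a median of -0.06, with 4 higher and 6 lower. Of 10000 random lists matched on mean signal, 96.2% had as high a median, which argues against a general rise in the signal of these probes. How much short RNA passed the RNeasy columns and the labelling was not tested. Whether short RNAs themselves were more abundant therefore stays undecided. The classes differed. The median was -0.16 for 55 SNORD genes (0 higher, 3 lower) and 0.03 for 40 SNORA genes (1 higher, 2 lower). For 12 SCARNA genes, those of Cajal body RNAs, it was 0.26 (3 higher, 1 lower).

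The 1566 changed genes were set against 3 explanations. Only 10 splits of the 6 arrays exist, too few for a share under 0.05: 1 split, the real one, gave as many genes, and by limma the highest other gave 0 (228 to 274 genes at an unadjusted p below 0.05, against 3125). Every other split mixes both groups, so a group difference widens its spread and lowers its count. The contrast therefore gives no measure of chance. Errors of single probes predict that a second probe goes either way, but in 91.5% of the 398 changed genes with a second kept probe it went the same way (364 genes, exact 95% interval 88.3% to 94.0%), against 67.0% of genes not called. In these 398 genes the median absolute log2 fold change was 0.85 for the tested probe. The second probe's median, counted in the tested probe's direction, was 0.57, so second probes gave smaller changes. A copy-number difference between the cell pools predicts runs of neighbouring genes that shift together, and camera called 0 of 349 blocks of 30 neighbouring genes (24 at an unadjusted p below 0.05), so the share of changed genes in such blocks was 0%. Position on the chip and the knockdown itself cannot be told apart, and an off-target effect of the hairpin was not tested.

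The fall of mitosis genes was set against a signal-dependent bias of the normalization. Of 10000 random lists matched on mean signal 0% had as low a median as -0.85, and the lowest was -0.27, which argues against that bias. An equal fall of all cell-cycle genes predicts the same median in the G1/S list, yet the mitosis median lay lower by a log2 difference of -0.72 (95% interval from resampling genes, -0.96 to -0.42). That interval holds the spread between genes and not the spread between arrays. An unequal fall of cell-cycle genes, as a change in cell division might give, was not tested. A specific fall of mitosis transcripts in shTCF7L1 cells stays a hypothesis, since chip position follows the groups and only an equal fall was tested.

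The lower TCF7L1 signal was set against noise of probes near background. Of the 1000 probes of nearest control signal 1% fell by as much (95% interval 0.481% to 1.83%), and their median was -0.05, which argues against noise alone. That interval treats the probes as independent and does not hold the spread between arrays. The difference did not pass in limma (adjusted p = 0.0800), and no knockdown array was above background. Whether and how far the transcript fell therefore stays open.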
